A study of Sphingomonas sp. LH128 with 6 samples.

How the data were processed

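Total RNA from 6 samples of *Sphingomonas* sp. LH128 was measured, 3 from nonstarved and 3 from starved cells, and each sample was hybridised to 1 array. Per the labels' protocols, cells were grown in triplicate 50 ml cultures, 5 ml portions were washed, and RNA was extracted from 1 ml of suspension from triplicate tubes of each condition. The labels do not say which tube came from which culture, so the p-values measure the spread between these samples. Per the labels, 4 µg of RNA was reverse transcribed with random primers in the presence of Cy3-labelled nucleotide. Starved cells had been kept in the magnesium sulphate solution for 4 h, per the labels.

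Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1 in 1 colour. The deposited scanner files hold spot intensities on a linear scale, not yet normalized between arrays. Per the file headers the processed signal is a background-subtracted, spatially detrended intensity in which low values are replaced by a small positive surrogate. Other flags in the deposited files, each 0 or 1, mark spots that were outliers, saturated or well above background. A table of the authors' processed values was also deposited, with centred values that track log2 signals in part. No aligner, annotation or genome build is given in the sources used here.

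Probe names in the starved files lacked the letter that tells the probes of a gene apart, so spots were matched between arrays by feature number, and the rest of the name and the control type were checked to be identical for every spot. There were 12863 gene spots and 536 control spots per array. The names consist of start and end coordinates, and the order of both gives the strand: 3459 genes lie on the plus and 3574 on the minus strand. All 7033 coding lengths are multiples of 3 and range from 69 to 7254 bp, with a median of 675 bp, and together they equal 89.2% of the span of the coordinates.

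The authors' table had 6925 rows, of which 6888 matched a gene and 37 a control feature. Its column medians were 0.01 for the first nonstarved column and 0 for the others. Differences between its starved columns tracked those of the log2 scanner signals (r between 0.941 and 0.978, slope between 0.810 and 0.863). Differences between its nonstarved columns did not (r between -0.069 and -0.020), and differences between columns of different groups gave r between 0.016 and 0.230. The change between groups had r = 0.004 with the scanner files across genes. Centring per gene cancels within a group, so it does not account for the mismatch of the nonstarved columns. Set against their group mean, the starved columns each followed the file of the same number (r of at least 0.947), while no nonstarved column followed any nonstarved file (r between -0.059 and 0.073). Whether the nonstarved scanner files are the arrays behind the nonstarved columns could therefore not be settled. What the values were centred on, their scale in the nonstarved columns and their direction between groups stay unknown, and the table was not used for any comparison.

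For each spot the log2 of the processed signal was taken, outlier-flagged spots were left out, and the spots of a probe were averaged, which concerned 20 probes with 11 spots each. Each array was then shifted so that the 75th percentile over its gene probes was 0. A probe was kept where it was well above background on all arrays of at least 1 group. This kept 9544 probes, 6990 detected in both groups, 2452 in the nonstarved group alone and 102 in the starved group alone. A further 2 probes were dropped because all their spots were flagged on an array. Kept probes of a gene were averaged on the log2 scale, giving 6013 genes, and 1020 genes were not tested. The spread over replicated spots of a probe had a median coefficient of variation between 9.84% and 17.1% per array.

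Starved and nonstarved arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Changes are starved minus nonstarved on the log2 scale. Where all probes of a gene were not well above background on every array of a group, the fold is given as a bound: the mean of the brighter group against the mean, per array, of the higher of the dim probe's own signal and the lowest signal of any probe well above background. Slide and scan were read from the headers. Each group lay on 1 slide and in 1 scan of its own, so neither could be fitted as a block.

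Before the data were examined, the comparison, its test, a rule for named genes and 27 gene lists, defined by product names and symbols, had been fixed. The files do not pair identifiers with gene names, so the lists could not be applied and no result is given for them. Of the rule for named genes, the parts that rest on product names or lists could not be used. What remained was the part that names, by identifier, the 2 genes with the largest rise and the 2 with the largest fall among those that passed the test, had separate groups and were well above background on every array. The part that names the genes with the largest bounds was not used, to keep the identifiers to that number, except that the highest bounds are given without them. Stretches, runs, neighbour correlations, 100-kb windows and 5 classes by signal were chosen after it was clear that no names were given.

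Stretches were at least 3 consecutive genes of the array on 1 strand, all past the threshold and changed at least 2-fold in the same direction; a gene that was not measured ended a stretch. Their number was compared with 1000 shuffles of the changes among measured genes. Runs and windows with at least 5 and 20 measured genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Intervals of correlations are 95% percentile intervals from 1000 resamplings of 100-kb windows. The same holds for the difference between classes among probes detected on all arrays. For the difference between classes in the main processing, single genes within each class were resampled 1000 times. Figures were drawn with matplotlib 3.10.9.

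The steps were tested on simulated data with the 6013 genes and the spread of this comparison, in which 200 genes were changed. The test recovered 54% of genes changed 1.5-fold, 92% at 2-fold, 98% at 4-fold and 100% at 8-fold, and called 8 unchanged genes. Far fewer genes were changed in the simulation than the 3827 called in the data, and both groups were given the same spread per gene. These rates therefore need not hold in the data. Of 20 stretches planted with 4-fold falls 19 were found, with 0 others, and the 1 planted window was called with 0 others. The genes were simulated independently, so close same-strand neighbours had an r of 0.011, against 0.591 in the measured data. The simulation therefore does not show how often false stretches or windows arise where neighbours change together.

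The alternatives were quantile normalization, a shift to the median, the 75th percentile over probes detected on all arrays, no filter and a stricter filter on dim probes, other variance models, the brightest probe of a gene, other thresholds, the replicate number as a block, and leaving out each array in turn. Normexp background correction with an offset of 50 used the median spot and background signals, because the files have no mean signal column. That version, cyclic loess normalization, other stretch thresholds and other window sizes were added after the data had been seen.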

Results

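RNA was measured in the bacterium *Sphingomonas* sp. LH128, which degrades the polycyclic aromatic hydrocarbon phenanthrene, on 6 single-colour custom microarrays. The 3 nonstarved samples were freshly washed cells from cultures grown in minimal medium with 2 g/l glucose to an optical density of 0.5. The 3 starved samples were cells washed the same way and kept for 4 h at 20 °C in a magnesium sulphate solution without a carbon source. The concentration of that solution is given as 0.01 M in the protocol label and as 0.01 mM in the design text, and the difference could not be settled here. The array carried 12663 probes for 7033 predicted coding sequences, called genes here, of which 5630 had 2 probes and 1403 had 1. Each gene is identified only by its start and end coordinate, and the files do not pair these identifiers with gene names. The coordinates run from 32 to 6493932 on a single axis whose genome build is not given in the sources used here.

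The 75th percentile of the spot signal was 193, 174 and 192 on the nonstarved arrays and 440, 562 and 599 on the starved arrays. Of the gene spots, 80.8%, 77.4% and 78.4% were well above background on the nonstarved arrays, against 75.5%, 56.3% and 86.2% on the starved arrays. No gene spot was saturated. Scaled probe values correlated across probes with r between 0.978 and 0.982 for pairs of nonstarved arrays and between 0.965 and 0.980 for pairs of starved arrays. Pairs from different groups gave r between 0.869 and 0.894. The number of arrays, 3 per group, limits the precision of every value.

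The comparison of starved with nonstarved cells addressed how transcription changed during short-term starvation. Of 6013 genes measured, 3827 (63.6%) changed, 1763 of them higher and 2064 lower in starved cells. The changes were often large, with 791 genes at least 2-fold higher and 966 at least 2-fold lower, and 70 genes at least 8-fold higher and 50 at least 8-fold lower. Whole blocks of adjacent genes moved together. In the main processing the steepest fall was that of 5 neighbouring genes, with a median log2 change of -5.43. The steepest rise was that of 4 neighbouring genes, with a median of 4.15 (n = 3 arrays per group). Which block fell most depended on the processing, and with normexp background correction another block fell more (-4.43 against -3.91). The median standard error of a gene's log2 change was 0.14, against a standard deviation of 1.14 for the changes across genes.

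These calls are from limma's moderated test with Benjamini-Hochberg adjusted p under 0.05. The 3 starved values lay entirely above or below the 3 nonstarved values in 4178 genes (69.5%), where chance would give 10%. The share of calls that were higher depended on the scaling, the filter and the choice of probes. It was 46.1% with the 75th percentile scaling, 57.7% after scaling to the median, 36.3% after scaling to the 75th percentile of probes detected on all arrays and 35.3% with another background correction (normexp). Those alternatives moved the median log2 change of all genes by 0.20, -0.18 and -0.13, so each change is relative to the other genes on the array. More genes were higher than lower with no filter on dim probes (1972 against 1851, 51.6% higher), with only probes detected on all 6 arrays (1874 against 1404, 57.2%) and with the brightest probe of each gene (1879 against 1837, 50.6%). All nonstarved arrays were on 1 slide and scan and all starved arrays on another, so slide and group cannot be told apart. Every change also rests on nonstarved scanner files that the nonstarved columns of the authors' processed table did not follow (r between -0.059 and 0.073, against at least 0.947 for the starved files).

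**Figure D1:**
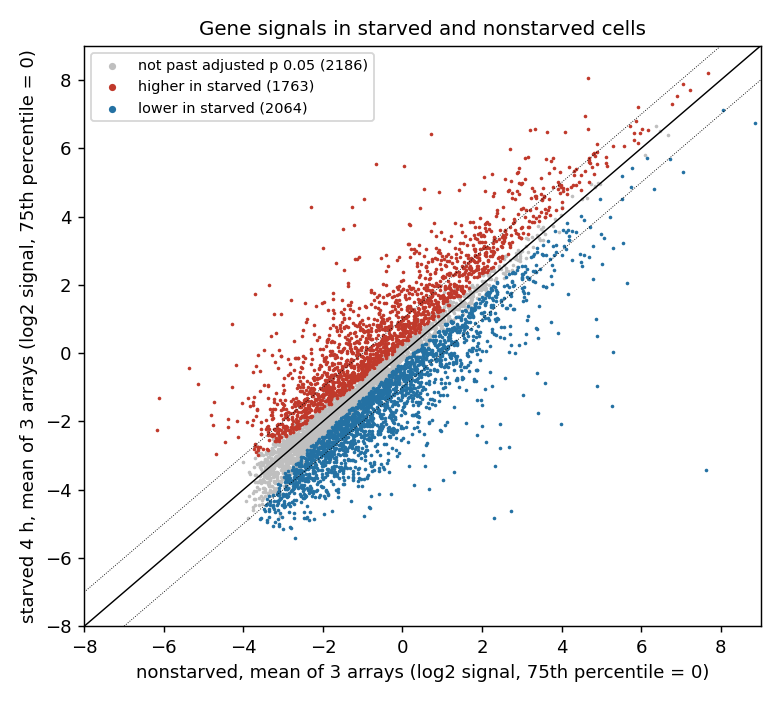
Each point is 1 of 6013 genes, with its mean scaled log2 signal over 3 nonstarved arrays on the x axis and over 3 starved arrays on the y axis. The solid line marks equal signal and the dotted lines a 2-fold change. Red marks the 1763 genes higher and blue the 2064 genes lower in starved cells at adjusted p under 0.05, and grey the others.

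The highest rise among genes measured on every array was that of 3344985_3345332, a gene of 348 bp on the plus strand. Its scaled log2 signal went from -2.30 ± 0.06 to 4.29 ± 0.19 (SD, n = 3 arrays each), a log2 change of 6.59 (SE 0.11, limma adjusted p = 8.79e-10). Gene 291147_290410, of 738 bp on the minus strand, rose by 6.23 (SE 0.08, limma adjusted p = 2.65e-10), from -0.67 ± 0.05 to 5.55 ± 0.08. Its 2 probes rose by 4.90 and 7.56. The steepest fall among genes measured on every array was that of 3794077_3794283, of 207 bp on the plus strand, which went from 5.26 ± 0.25 to -1.55 ± 0.17, a log2 change of -6.81 (SE 0.14, limma adjusted p = 2.52e-09). Gene 2444592_2445044, of 453 bp on the plus strand, changed by -5.85 (SE 0.14, limma adjusted p = 4.86e-09), from 4.88 ± 0.14 to -0.97 ± 0.27, and the weaker of its 2 probes changed by -5.70. Over 17 alternatives the log2 changes of these 4 genes, in the order given, ranged from 5.25 to 6.78, 4.90 to 6.42, -7.09 to -5.99 and -6.15 to -5.19. Genes 3344985_3345332 and 3794077_3794283 rest on 1 probe each, so the choice of probe and the filter on dim probes could not alter their log2 changes.

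Genes in a row on the same strand often changed together. At least 3 consecutive genes on 1 strand, each at least 2-fold higher, formed 45 stretches that held 160 genes. A further 36 stretches, with 139 genes, were made of genes at least 2-fold lower. Shuffling the changes among the measured genes 1000 times gave on average 3.71 rising and 6.74 falling stretches, and at most 11 and 16. The permutation p was 0.001 in both directions, the smallest that 1000 shuffles can give. The longest rising stretch held 6 genes and the longest falling stretch 8. With normexp background correction the counts were 21 rising and 20 falling stretches, and 14 falling stretches were left when only probes detected on all 6 arrays were used.

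The steepest falling stretch in the main processing spanned positions 1028854 to 1036184 on the plus strand. Its 5 genes, in order, had log2 changes of -2.70, -2.85, -7.37, -11.06 and -5.43, with standard errors between 0.09 and 0.30. The gene in the middle was not well above background on any starved array, so its fall was at least 75.8-fold. The stretch median of -5.43 was the same with that gene at its bound. In the gene with the change of -11.06, one probe was well above background on 2 of the 3 starved arrays and the other on 1. Their mean starved signals were 44.5 and 54.3, so the exact size of this fall also rests on signals near background. An unmeasured gene on the opposite strand followed, and after it the next 2 measured genes on the plus strand were also lower. The first changed by -5.61 (SE 0.15), with a probe well above background on 2 of the 3 starved arrays. The second had a measured change of -7.12 (SE 0.32), but only 1 of its probes was well above background on 1 starved array, so its size is set largely by signals near background. The median of the stretch was -2.49 when only probes detected on all 6 arrays were used, which left 3 of its genes. Between 2442947 and 2445044, also on the plus strand, 3 genes changed by -4.46, -5.26 and -5.85, and their median was -3.03 with the brightest probe of each gene. In a falling stretch from 5104846 to 5107313, 3 genes changed by -4.13, -4.53 and -4.77. With normexp background correction the medians of these 3 falling stretches, in the order given, were -3.91, -4.43 and -3.19. They were -5.43, -5.62 and -4.55 with cyclic loess normalization, and -2.49, -4.46 and -4.53 with only probes detected on all 6 arrays. The first stretch was not the steepest in any of these settings.

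The steepest rising stretch lay between 288183 and 291752 on the minus strand. In map order its 4 genes rose by 4.38, 3.92, 6.23 and 1.09 on the log2 scale, with standard errors between 0.08 and 0.12. Their median of 4.15 was 2.88 with normexp and 3.40 with no filter on dim probes. With only the brightest probe of each gene, the weakest of these calls was lost (limma adjusted p = 0.0529). From 1520463 to 1524891 on the minus strand, 4 genes rose by a median of 3.39. One of them was not well above background on any nonstarved array and rose at least 6.35-fold. With it at that bound the median was 2.54, and with normexp background correction it was 1.21. A stretch of 4 short genes from 4565634 to 4566807 on the plus strand rose by 2.58, 3.31, 3.55 and 1.89, with a median of 2.95, or 1.91 with normexp.

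**Figure D2:**
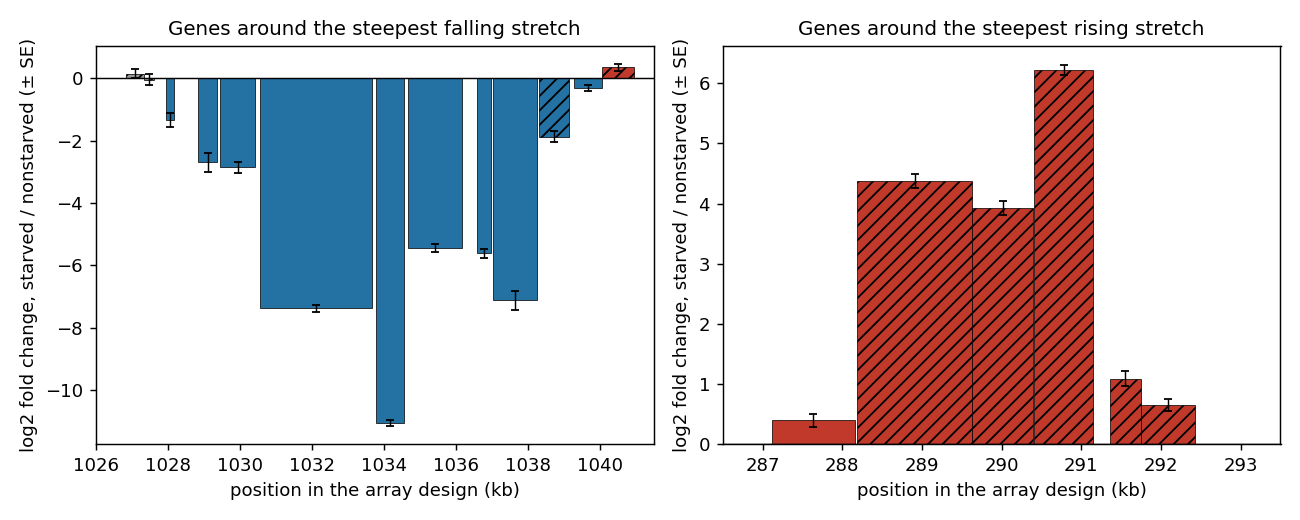
Bars give the log2 fold change (starved over nonstarved, ± SE, 3 arrays per group) of the genes around the steepest falling stretch (left) and rising stretch (right), with each bar as wide as its gene and its position in kb on the x axis. Blue bars are lower and red bars higher at adjusted p under 0.05, grey bars are neither, and hatched bars lie on the minus strand. In the falling stretch the changes run from -2.70 to -11.06, and in the rising stretch from 1.09 to 6.23. The exact size of the largest fall rests on starved signals near background.

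Longer runs of closely spaced genes were tested as groups. A run was a series of genes on 1 strand with less than 50 bp between neighbours, and 71 runs had at least 5 measured genes. By limma's camera test with a preset correlation of 0.01, 7 runs were higher and 4 lower in starved cells. With an estimated correlation camera called 0 runs (lowest adjusted p = 0.650, and 3 runs with an unadjusted p under 0.05). The number of lower runs was 2 without the second nonstarved array, 1 with the brightest probe of each gene and 10 with no filter on dim probes. Between 11927 and 17316 on the minus strand, all 12 genes of a run were lower, with a median of -1.94 (camera adjusted p = 1.65e-04; adjusted p = 0.650 with an estimated correlation). All 10 measured genes of a run from 659312 to 668655 were lower, with a median of -1.15. All 6 measured genes of a run from 5927142 to 5931268 were higher, with a median of 2.53. Every member was higher in 4 of the 71 runs and lower in 4.

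Neighbouring genes shared their change more when they lay close together on the same strand. Across 1825 pairs of same-strand neighbours less than 50 bp apart, log2 changes correlated with Pearson's r of 0.591 (95% bootstrap interval 0.534 to 0.641). At 50 to 300 bp r was 0.371 (0.261 to 0.480, 1188 pairs), and at 300 bp or more it was 0.142 (-0.001 to 0.280, 191 pairs). Across 870 pairs of neighbours less than 50 bp apart on opposite strands, r was 0.058 (-0.011 to 0.122). On opposite strands it was 0.105 (0.036 to 0.178, 930 pairs) at 50 to 300 bp, an interval above 0, and -0.021 (-0.175 to 0.127, 196 pairs) at 300 bp or more. The difference between both kinds of close pairs was 0.533 (0.449 to 0.611). These are correlations across gene pairs, which are not independent replicates, and the intervals come from resampling 100-kb windows.

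**Figure D3:**
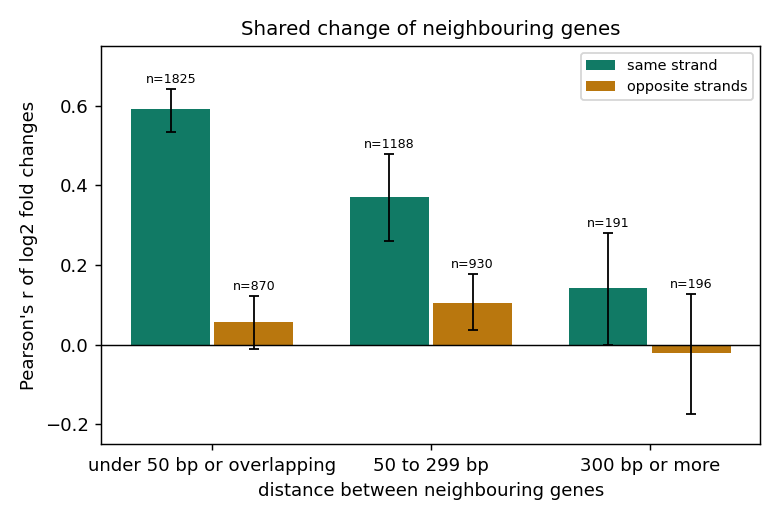
Bars give Pearson's r between the log2 fold changes of neighbouring genes on the same strand (green) or on opposite strands (orange), by the distance between them, with 95% bootstrap intervals and the number of pairs. Same-strand neighbours under 50 bp apart reach 0.591, and the value falls to 0.371 and 0.142 at larger distances.

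Some genes were seen in 1 state only. In starved cells, 49 genes measured in nonstarved cells were not well above background on any array, and 44 of them passed the test. For 46 of the 49 a bound could be given, with a median of at least 1.56-fold lower and a highest value of at least 75.8-fold. In nonstarved cells, 8 genes were not well above background on any array. All 8 passed the test, with a median bound of at least 4.22-fold higher and a highest bound of at least 11.8-fold. The detection limit differed between arrays, since the second starved array had a negative control signal of 20.4 against 2.57 to 8.60 on the others.

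Brightly hybridising genes tended to be higher and dim ones lower in starved cells. Genes were put in 5 classes of equal size by their mean signal over all arrays. In the brightest class, 290 genes were at least 2-fold higher and 130 at least 2-fold lower, with a median log2 change of 0.34. In the dimmest class 48 were at least 2-fold higher and 280 at least 2-fold lower, with a median of -0.38, or -0.36 with its 56 genes that have only a bound set to it. The medians of the classes between these were -0.22, -0.11 and 0.02. The difference between the brightest and the dimmest class was 0.72 (95% bootstrap interval 0.63 to 0.80, from resampling single genes as if independent). It was 0.46 without the second starved array, 0.27 among probes detected on all 6 arrays, 0.32 and 0.23 after quantile and cyclic loess normalisation, and -0.21, the opposite direction, when no filter on dim probes was applied.

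Both probes were kept and could be compared in 3531 of the 6013 genes, and their changes correlated with r = 0.698 across genes. Among 2455 such genes that passed the test, the 2 probes changed in the same direction in 2185 (89.0%). Among the 1125 that changed at least 2-fold they did so in 1100 (97.8%). Genes passed the test on the mean of these same 2 probes, which favours probes that agree.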

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

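In this part, the test on other splits of the arrays and the test on neighbouring genes were chosen after the result was seen. Groups of 3 arrays were not examined for single outlying arrays. Among 60 control features, the bright corner spots stood out because they were well above background on all arrays and higher on every starved array after scaling, by 0.64 on the log2 scale (from 0.54 to 1.18). Their unscaled median signals were 224, 284 and 308 on the nonstarved arrays and 1187, 1183 and 1230 on the starved arrays. They are control spots of the array design, not gene probes. Being higher on every starved array selects rises only, so control features that fell were not picked. Some other control features changed more, in both directions. Feature ETG05_36762 changed by 1.73 (from -5.84 to -4.11) and feature DCP_22_0 by -1.59 (from -3.23 to -4.82). Neither was well above background on all starved arrays, and the cause of these changes was not tested.

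The number of genes changed, 3827, was weighed against technical causes that go with the slide. Blocks of rows and columns explained 0.361% of the variance of the spots' changes (adjusted R squared). The processed signal had already been spatially detrended, so this low share cannot decide on the position on the array. A hybridisation or scan effect unrelated to signal level gives no reason for neighbours on 1 strand to change together, yet their r exceeded that of opposite-strand neighbours by 0.533. An effect that depends on signal level was not excluded, since whether close neighbours had similar signals was not tested. The r of close same-strand neighbours was 0.596 with cyclic loess normalization, against 0.591 in the main processing. With 10 splits of the 6 arrays into 3 and 3, a share under 0.05 cannot be reached. The real split gave 3827 genes, and the highest of the others gave 0 with limma (at most 149 at an unadjusted p under 0.05). Each other split mixed the groups on both sides, so the difference between groups added to its spread. Few calls there would follow from any large group difference, whatever its cause. Since 0 slides hold both groups, a batch of culture, RNA extraction or labelling that went with the slide cannot be told apart from starvation, the biological difference named by the design, and either could account for the changes.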

How the results depend on the processing

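Stretches, neighbour correlations, signal classes, runs and windows, normexp and cyclic loess were chosen after seeing the data. Over 364 alternative values of 20 results, 322 stayed close to the value reported. Close meant tested genes and stretches on the same side of the threshold, counts within 1.5 times, other values within their spread. Part of these 322 could not have changed. Shifts of whole arrays, other variance models and the replicate block leave neighbour correlations and class differences as they are. Window and run tests do not use the variance model, and the 2-fold setting counts the same stretches. Of the values that were not close, 28 became weaker, 3 stronger, 10 moved and 1 reversed. A count within 1.5 times can still turn the balance, as after the median shift (2181 higher, 1597 lower). The 1757 genes changed at least 2-fold were checked under 5 other scalings and background corrections. Between 97.6% and 99.8% of them stayed past the adjusted p threshold in the same direction. The 4 named genes did so under all 17 alternatives. A 2-fold change was not required in this check, and 2 of the 5 settings only shift whole arrays, which can hardly remove such calls. The threshold set the number of genes: 1757 (791 higher, 966 lower) at 2-fold or more and 1792 (872 and 920) tested against 1.5-fold. Leaving out 1 array gave 3406 to 3948 genes. Stretches numbered 21 rising and 20 falling with normexp, 14 falling with probes detected on all arrays, 79 and 82 for changes of 1.5-fold and 10 and 11 for 4-fold. The correlation of close same-strand neighbours was 0.527 with normexp, 0.533 with probes detected on all arrays and 0.476 with the brightest probe. The difference between the brightest and dimmest class was 0.94 with normexp, 0.32 with quantile and 0.23 with cyclic loess normalization, 0.27 with probes detected on all arrays, 0.46 to 0.91 when 1 array was left out and -0.21, reversed, with no filter. Fewer genes were tested with the stricter filter and more with none; for the others the cause was not tested.

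Same-numbered arrays had correlations of their deviations from the group mean of -0.083, -0.175 and -0.016. Arrays of different numbers gave values between -0.155 and 0.201. With so few arrays these values cannot tell whether same-numbered samples were paired. With the replicate block 3618 genes were called (1658 higher, 1960 lower). Not run were slide and scan blocks, which hold 1 group each, the authors' table, normexp on mean signals, which the files lack, and all gene list tests. Signal over background limited the second starved array most, where the 75th percentile was 27.5 times the negative control signal, against 51.1 to 95.9 on the others.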

Other observations

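In this part, the test of the filter on dim probes, which was also restated after its values were seen, the test of single probes and the test on the genes of the stretch without a clear signal were chosen after their results were seen. Of 65 windows of 100 kb along the coordinates, 1 was higher and 3 were lower in starved cells by camera at the preset correlation. With an estimated correlation camera called 0 windows (lowest adjusted p = 0.841, and 3 windows with an unadjusted p under 0.05). The lowest was 600001 to 700000, with a median log2 change of -0.61, 51 of its 89 genes lower and 9 higher (camera adjusted p = 0.0139; adjusted p = 0.994 with an estimated correlation). The window from 1 to 100000 had a median of -0.54 (50 lower and 14 higher of 93). From 5900001 to 6000000 the median was 0.31. The count was 2 without the first nonstarved array, 1 without the first starved array and 0 with probes detected on all arrays.

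It was asked, before the values were seen, whether neighbours transcribed away from each other share their change more than neighbours transcribed towards each other. For pairs under 300 bp apart, r was 0.104 (95% bootstrap interval 0.037 to 0.176, 887 pairs) for the former and 0.075 (0.004 to 0.149, 913 pairs) for the latter. The difference of 0.030 (-0.062 to 0.121) left the hypothesis open.

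The rise of the change with signal level was weighed against 2 technical explanations. The filter kept 2452 probes that were well above background on all nonstarved but not all starved arrays. In the other direction it kept 102, an imbalance that could make dim genes look lower. With no filter the difference between classes was -0.21, the opposite direction, but that setting adds genes at the floor. Among probes detected on all 6 arrays it was 0.27 (0.17 to 0.36), but that filter drops those probes and so also decides which dim genes stay. As these disagree, the filter stays open, and so do background correction and scaling: over 5 alternatives the lowest difference was 0.23, neither reversed nor above the 0.3 set before as the bound for excluding them. A response that differs between abundant and rare transcripts was not tested.

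The stretch from 1028854 to 1036184, the steepest fall in the main processing, might reflect DNA missing from the starved cultures. Of its 5 genes, 3 kept a probe well above background on all 3 starved arrays, which had been set before as enough to argue against this. In each of these 3 genes, however, it was 1 probe alone, and the other probe was above background on 0, 1 and 1 starved arrays, so signal from other transcripts on the first probe was not excluded and the explanation stays open. Of the other 2 genes, 1 had no probe above background on any starved array and 1 had probes above it on some. A single misbehaving probe per gene is argued against by the 4 genes in which both probes fell at least 4-fold, and no biological explanation was tested.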
